A study of Mus musculus with 6 samples.

How the data were processed

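RNA was measured by sequencing in 6 libraries from mouse bone marrow derived macrophages of the C57BL/6 strain. Per the labels' protocols, the marrow cells were grown with GM-CSF and given DMSO or RIP1i overnight from day 7. Total RNA was then extracted with Trizol, and libraries were built with an Illumina TruSeq RNA kit. The groups were taken from the treatment named in each sample's labels, which gave 3 DMSO and 3 RIP1i libraries. The labels name neither the RIP1i compound nor its dose, and they do not say whether the 3 replicates of a group were separate cultures or animals. P-values therefore measure only the spread between these libraries, which may be technical.

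The authors deposited a table of raw read counts per gene and a table of FPKM values for the same genes and libraries. Per the submitters' processing notes, CASAVA 1.8.4, STAR 2.5.3a, featureCounts, Subread 1.4.6-p3 and DESeq2 1.14.0 were used with the mouse build mm10. The role of each tool, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Counts of near-identical or overlapping genes, such as members of the Ifit, Mx and H2 families, may therefore share reads. The count values were whole numbers with different library totals. The deposited FPKM values were the counts divided by a gene-specific factor and multiplied by a library factor. Over 6011 well-covered genes, that library factor differed from the inverse of the median-of-ratios size factor by at most 0.000262%. The FPKM values therefore hold the same reads under another scaling and add no measurement of their own. The table listed 52459 genes, of which 27262 had at least 1 count in the 6 libraries. Of the symbols, 26 had been turned into dates, as spreadsheet software does, and 4 of these entries shared a date with another. They stayed in the test under those names, and none of them is named in the text.

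Library totals ran from 40264902 to 44862310 counts. Genes with too few reads for a test were removed with the default filterByExpr of edgeR (minimum count 10, minimum total 15), which left 14857 genes. TMM factors ran from 0.978 to 1.01. The comparison of RIP1i with DMSO was made with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, 2-sided, with treatment as the only term and all 6 libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold. A log2 fold change is RIP1i minus DMSO, its standard error (SE) was taken from the F statistic, and its 95% confidence interval from the t distribution with the degrees of freedom of the fit. Levels are CPM (read counts scaled by library size) with TMM scaling, as mean ± SD. They cover the spread between libraries, and whether this includes the preparation of the cells is not known.

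A set of 34 gene lists was fixed before the data were examined, covering antigen presentation, cytokine and interferon responses, RIP1 signalling, metabolism, stress, markers of cell types that such a culture can hold, and RNA quality. They held 580 different genes, all of them in the table and 536 of them tested. Lists with at least 3 tested members (33 of 34) were tested with camera in limma 3.58.1, 2-sided, on log2 CPM with a prior count of 2. Camera compares the genes of a list with all other genes. Its preset inter-gene correlation of 0.01 was the main setting, and adjusted p was taken over the 33 lists. Camera with a correlation estimated from these libraries, and fry, which tests whether the genes of a list move on balance in 1 direction, were alternatives. The level of a list in a library is the mean over its genes of log2 CPM after each gene was centred on its mean over the 6 libraries. Group differences in such levels were tested with an exact 2-sided permutation test, for which 0.1 is the smallest p that 3 against 3 libraries allow.

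The rule for named genes was also fixed before the data were examined. It takes 18 focus genes of RIP1 signalling, antigen presentation and macrophage activation whatever their result. It takes genes past the adjusted threshold with mean CPM of at least 1 and no overlap between the groups, leaving out unnamed and predicted genes and pseudogenes, up to 12 in each direction. Where none passes, as here, it takes the 5 with the smallest p in each direction, named as not passing, and they keep the other conditions of the rule. It takes up to 4 members of each described list with the smallest p. Not every gene that the rule takes is named in the text. Genes outside the rule are identified as such where they appear.

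Alternatives fixed before the data were examined were median-of-ratios and upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, thresholds of 0.01 and 0.1, and limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with mean FPKM of at least 0.5 or with no filter. A surrogate variable from sva 3.50.0 as a covariate, leaving out the 2 libraries with extreme stromal marker levels, and the stromal marker level as a covariate were added after the data had been seen. The labels give both groups the numbers 1 to 3 without saying what a number stands for.

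The test was tried on simulated counts with the means, dispersions and library sizes of this comparison, with 200 of 14857 genes changed in each of 10 simulations. It recovered 17.3% of genes changed 1.25-fold, 55.4% of those changed 1.5-fold and 71.1% of those changed 2-fold. Of 1051 calls, 95 (9.04%) were of unchanged genes. In simulations without any change, camera with the preset correlation called 0 lists, but the simulated genes varied independently of each other. No 2 libraries agreed within sampling noise, since the chi-square of their counts over its degrees of freedom was 11.2 or more for every pair. Coordinates are those of the GRCm38 (mm10) annotation of GENCODE release M21, matched by symbol. Of the tested genes, 14460 were found there.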

Results

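The transcriptome of mouse bone marrow derived macrophages was compared between cultures given RIP1i and cultures given DMSO, the solvent control. The cells had been grown from C57BL/6 marrow with GM-CSF, a cytokine that drives marrow cells towards macrophages and related myeloid cells, and were treated overnight from day 7. RIP1 kinase, encoded by Ripk1, relays signals of the TNF receptor to NF-kB and to cell death. The comparison addresses how RIP1i alters macrophage gene expression. Each group held 3 libraries, with totals of 44075389, 40264902 and 44862310 counts for DMSO replicates 1 to 3 and 40729238, 41509863 and 42378138 counts for RIP1i replicates 1 to 3. Between 21687 and 22193 genes had at least 1 count in a library. Transcripts known from macrophages stood at high levels in both groups. Lyz2, which encodes lysozyme, stood at 49723 ± 3966 CPM in DMSO and 45252 ± 4857 CPM in RIP1i (SD, n = 3 each). The chemokine gene Ccl6 stood at 13462 ± 334 and 14327 ± 256 CPM, and the elastase gene Mmp12 at 9381 ± 104 and 10616 ± 978 CPM.

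No gene passed the test for a difference between RIP1i and DMSO. With edgeR's quasi-likelihood test, 0 of 14857 genes had an adjusted p under 0.05, with 0 higher, 0 lower and 0 changed at least 2-fold, and the smallest adjusted p was 0.777. At an unadjusted p under 0.05 there were 923 genes, of which 534 were fitted higher and 389 lower in RIP1i, where 742.85 would be counted by chance. On the same genes DESeq2 called 2 and limma-voom called 0. The fitted differences were small, with a median absolute log2 fold change of 0.075. The 95% confidence interval lay within 1.5-fold in either direction for 10841 genes (73.0%) and within 2-fold for 13161 genes (88.6%). Among 8535 genes with a mean of at least 10 CPM, 8359 (97.9%) had intervals within 1.5-fold. The RIP1i and DMSO libraries did not overlap for 2012 genes (13.5%), where chance gives 10%.

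The genes of the RIP1 pathway itself stood at nearly equal levels. Ripk1 (chromosome 13, 34002363 to 34037147, plus strand) was at 156 ± 5.55 CPM in DMSO and 155 ± 7.32 CPM in RIP1i (SD, n = 3), a log2 fold change of -0.0032 with a 95% interval from -0.12 to 0.11. Ripk3, the partner kinase of RIP1 in necroptosis, had a log2 fold change of 0.015 ± 0.050 (SE). Mlkl, which encodes the protein that ruptures the membrane in necroptosis, had 0.046 ± 0.087. Of the 22 measured RIP1 death-signalling components, 11 were fitted higher and 11 lower, and none passed (camera adjusted p = 0.751). The smallest p-values in that list belonged to Zbp1, a sensor of Z-form nucleic acids, at -0.22 ± 0.085, and Rnf31, a subunit of the linear ubiquitin ligase, at -0.16 ± 0.062.

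**Figure D1:**
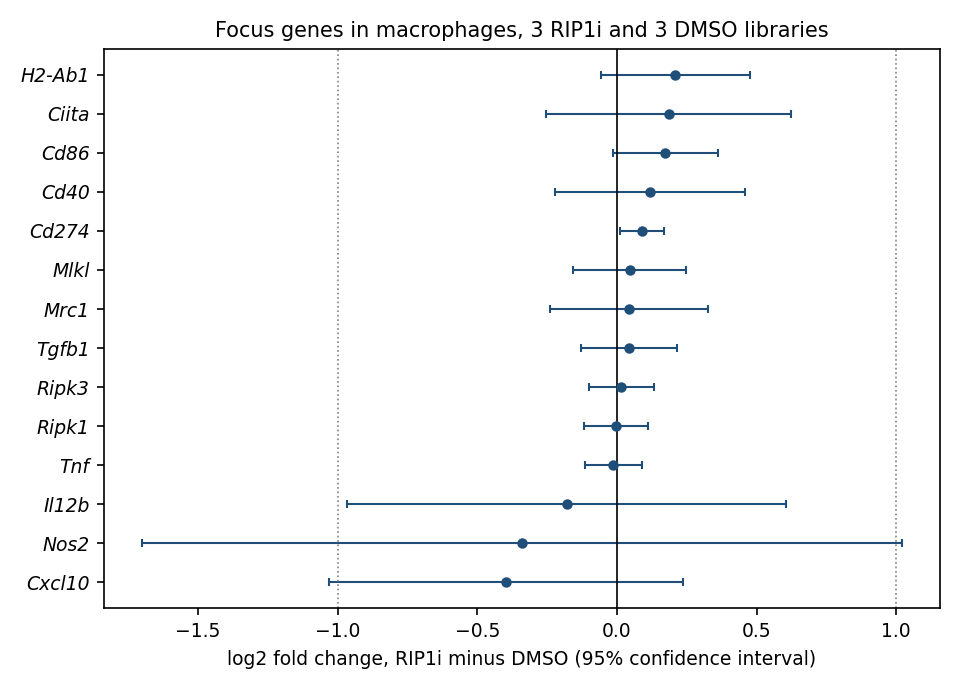
Log2 fold change of tested focus genes, RIP1i minus DMSO, on the horizontal axis, with genes on the vertical axis, points for the edgeR estimate from 3 libraries per group and bars for the 95% confidence interval. Of the genes shown, Cd274 alone has an interval that excludes 0 (0.011 to 0.17), and its adjusted p was 0.777. Dotted lines mark a 2-fold change.

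The focus genes of MHC class II and costimulation, H2-Ab1, Ciita, Cd86 and Cd40, were fitted slightly higher in RIP1i without passing. H2-Ab1 (chromosome 17, 34257689 to 34269419, plus strand), a chain of MHC class II, was at 925 ± 136 CPM in DMSO and 1070 ± 112 CPM in RIP1i (SD, n = 3), a log2 fold change of 0.21 with an interval from -0.057 to 0.48, and 0.11 without RIP1i replicate 2. Ciita, the transactivator of MHC class II genes, had 0.19 with an interval from -0.25 to 0.62, and -0.046 without RIP1i replicate 2. The costimulatory ligand Cd86 had 0.17 (-0.014 to 0.36) and the receptor Cd40 0.12 (-0.22 to 0.46), or 0.072 and 0.011 without that library. Cd274 (chromosome 19, 29367455 to 29388095, plus strand), which encodes the inhibitory ligand PD-L1, was at 236 ± 2.22 CPM in DMSO and 251 ± 1.71 CPM in RIP1i (SD, n = 3), higher in 3 of 3 RIP1i libraries. Its log2 fold change was 0.089 (0.011 to 0.17), with an edgeR adjusted p of 0.777.

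All 10 MHC class II presentation genes were fitted higher in RIP1i, with H2-Aa at 0.23 ± 0.099 and Cd74, the invariant chain, at 0.17 ± 0.087. None had an unadjusted p under 0.05, and the list missed the threshold (camera adjusted p = 0.0529, and adjusted p = 0.809 with an estimated correlation). It passed with 2 other scalings and without a filter (adjusted p from 0.0394 to 0.0475), and without DMSO replicate 3, RIP1i replicate 1 or RIP1i replicate 3 (adjusted p = 3.84e-05, 0.0418 and 0.00221), but not with the stricter filter (adjusted p = 0.0800). Its level was -0.068 ± 0.21 in DMSO and 0.068 ± 0.23 in RIP1i (SD, n = 3, exact permutation p = 0.5), and the difference of 0.14 was 0.25 without DMSO replicate 3, 0.23 without RIP1i replicate 3, 0.083 without DMSO replicate 1, 0.053 without DMSO replicate 2 and 0.00030 without RIP1i replicate 2. Without the 2 libraries of extreme stromal marker level it turned to -0.078 (camera adjusted p = 0.728). These 2 were also the lowest DMSO and the highest RIP1i library in this list, so leaving them out had to lower the difference. Of the T cell costimulatory ligands 9 of 11 were fitted higher (adjusted p = 0.113), among them Icam1, an adhesion ligand, at 0.13 ± 0.036, and Tnfsf4, which encodes OX40 ligand, at 0.43 ± 0.18. In the list of T cell inhibitory ligands 4 of 11 were fitted higher (adjusted p = 0.948), among them Havcr2, which encodes the receptor TIM-3, at 0.16 ± 0.053. The MHC class I presentation genes were split into 11 fitted higher and 10 lower (adjusted p = 0.639), with Erap1, a peptide-trimming protease, at 0.11 ± 0.041. The difference in the level of that list was 0.0044 and turned to -0.0016 and -0.0074 with the 2 other scalings, which shift every list by nearly the same amount, so its sign carries no information.

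Genes of macrophage activation gave no call in either direction. Tnf was at 46.3 ± 1.60 CPM in DMSO and 45.9 ± 1.19 CPM in RIP1i (SD, n = 3), a log2 fold change of -0.013 (-0.12 to 0.090). Weakly expressed genes, at 1.07 to 2.47 CPM in both groups, had wide intervals. These were Il12b at -0.18 (-0.97 to 0.61), Nos2 at -0.34 (-1.70 to 1.02) and Cxcl10 at -0.40 (-1.03 to 0.24). Without DMSO replicate 2, Nos2 was at 0.45 and Cxcl10 at -0.055, and without DMSO replicate 3, Il12b was at 0.27. Of the M1-type inflammatory genes 11 were fitted higher and 12 lower (adjusted p = 0.592), with the chemokine Ccl5 at -0.26 ± 0.097. The mannose receptor gene Mrc1 had 0.044 (-0.24 to 0.33), and Tgfb1 had 0.043 (-0.13 to 0.22). Of the M2-type genes 13 were fitted higher and 8 lower (adjusted p = 0.751). Ccl17, a chemokine that attracts T cells, was at 418 ± 37.0 CPM in DMSO and 515 ± 26.5 CPM in RIP1i (SD, n = 3), a log2 fold change of 0.30 ± 0.071, Clec7a, the receptor dectin-1, had 0.22 ± 0.060, and Stab1, a scavenger receptor gene, had -0.23 ± 0.076. Another 3 focus genes were too weakly expressed to be tested. Cxcl9 had 5 to 15 counts in the DMSO libraries and 1 to 5 in the RIP1i libraries, Arg1 had 0 to 17 and 1 to 6, and Il10 had 0 or 1 in every library. These 3 genes were removed by the filter, so no difference was estimated for them.

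The 10 genes with the smallest p-values under the naming rule all had an adjusted p of 0.777 and none passed. Arhgap4 (chromosome X, 73891442 to 73921870, minus strand), which encodes a GTPase-activating protein, was at 57.9 ± 0.826 CPM in DMSO and 48.3 ± 0.615 CPM in RIP1i (SD, n = 3). Its log2 fold change was -0.26 ± 0.036 (SE) in edgeR, and DESeq2 gave -0.27 ± 0.058 with an adjusted p of 0.0449. Pde1b, a cyclic nucleotide phosphodiesterase gene, was fitted at -0.39 ± 0.079, the adaptor gene Fyb at -0.26 ± 0.053, Mx1, an interferon-induced GTPase gene, at -0.40 ± 0.081, and Padi4, a peptidylarginine deiminase gene, at -0.29 ± 0.061. In the other direction lay Qpct, which encodes a glutaminyl cyclase, at 0.24 ± 0.044, Man1a, a Golgi mannosidase gene, at 0.26 ± 0.049, Ubb, a polyubiquitin gene, at 0.24 ± 0.045, Erg28 at 0.23 ± 0.044 and Sgo2a, a shugoshin gene, at 0.29 ± 0.057. The other gene called by DESeq2, Gm10801, lies outside the naming rule and was chosen after its values were seen. This predicted gene was at 0.354 ± 0.048 CPM in DMSO and 1.59 ± 0.922 CPM in RIP1i (SD, n = 3), a log2 fold change of 2.16 with an adjusted p of 0.0449 in DESeq2 and 0.777 in edgeR.

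At the level of gene lists, camera with the preset correlation called 4 of 33 lists, 1 lower and 3 higher in RIP1i. None of the 4 was called with a correlation estimated from these libraries, where the smallest adjusted p of any list was 0.809, or by fry, where it was 0.440.

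The type I interferon response list was the one called lower. All 28 measured members were fitted lower, 7 of them at an unadjusted p under 0.05, and in 10 of them every RIP1i library lay below every DMSO library. Camera gave an adjusted p of 8.14e-09, against an adjusted p of 0.809 with an estimated correlation. No member passed over all genes tested, and 1 passed when adjusted over the list alone. That was Mx1 (chromosome 16, 97447035 to 97462907, minus strand), at 16.9 ± 0.847 CPM in DMSO and 12.9 ± 1.22 CPM in RIP1i (SD, n = 3), with an adjusted p of 0.040 over the list in edgeR. Ifit2 and Ifit3, interferon-induced RNA-binding protein genes, had log2 fold changes of -0.51 ± 0.17 and -0.66 ± 0.24, and Mx2 had -0.49 ± 0.18. The list level was 0.16 ± 0.15 in DMSO and -0.16 ± 0.34 in RIP1i (SD, n = 3), a difference of -0.32 on the log2 scale (exact permutation p = 0.2). RIP1i replicate 2 stood apart at -0.54, while RIP1i replicates 1 and 3, at 0.016 and 0.053, lay beside DMSO replicate 3 at 0.019. Without RIP1i replicate 2 the difference was -0.12 and the call was kept (camera adjusted p = 0.00207). Without RIP1i replicate 2 and DMSO replicate 2 the call was lost (camera adjusted p = 0.242). These were the libraries with the lowest and the highest level of stromal cell markers. They were also the lowest and the highest in the interferon list itself, so leaving them out had to raise the difference, whatever its cause. The interferon gamma target list, with 17 of 23 members fitted lower, was not called (adjusted p = 0.379), and its 4 members with the smallest p went both ways, Icam1 at 0.13 ± 0.036 and Cd274 at 0.089 ± 0.034, Irf8 at -0.092 ± 0.040 and Fcgr1 at -0.27 ± 0.12.

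Cholesterol synthesis genes were called higher as a list. Of 22 members, 20 were fitted higher, 9 members had an unadjusted p under 0.05, and none passed alone or when adjusted over the list alone. Hmgcs1 (chromosome 13, 119690379 to 119708260, plus strand), which encodes the synthase at the start of the mevalonate pathway, was at 139 ± 2.84 CPM in DMSO and 161 ± 9.90 CPM in RIP1i (SD, n = 3), a log2 fold change of 0.21 ± 0.051. Sqle, squalene epoxidase, had 0.17 ± 0.050, and Msmo1, a sterol oxidase, 0.20 ± 0.061. Camera gave an adjusted p of 1.56e-06, against an adjusted p of 0.809 with an estimated correlation. The list level differed by 0.10 (exact permutation p = 0.3), with RIP1i replicate 2 at -0.077, below DMSO replicates 1 and 2 at -0.050 and 0.0044. It was 0.15 without RIP1i replicate 2 and 0.052 without RIP1i replicate 3, and the call was kept in both cases. Without the 2 libraries of extreme stromal marker level it was 0.18 and the call was kept with the preset correlation (camera adjusted p = 2.20e-08). These 2 were also the highest DMSO and the lowest RIP1i library in this list, so leaving them out had to raise the difference.

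Cell cycle genes were also called higher as a list, with all 32 members fitted higher and 4 at an unadjusted p under 0.05. Ccnb1, which encodes the mitotic cyclin B1, was at 23.9 ± 0.226 CPM in DMSO and 27.6 ± 0.863 CPM in RIP1i (SD, n = 3), a log2 fold change of 0.21 ± 0.045. Ccna2, cyclin A2, had 0.20 ± 0.083 and Pcna, the replication clamp, 0.11 ± 0.048. Camera gave an adjusted p of 1.68e-05, against an adjusted p of 0.809 with an estimated correlation, and no member passed when adjusted over the list alone. The difference of 0.10 in list level (exact permutation p = 0.3) was 0.051 without DMSO replicate 1 and 0.045 without RIP1i replicate 2, and either omission ended the call (adjusted p = 0.0627 and 0.101). It was 0.15 without RIP1i replicate 3. Without the 2 libraries of extreme stromal marker level it was lost too (adjusted p = 0.144).

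The unfolded protein and ATF4 response list was the last one called higher, with 21 of 22 members fitted higher and 3 at an unadjusted p under 0.05. Slc7a11, the cystine transporter gene, was at 330 ± 21.7 CPM in DMSO and 398 ± 26.8 CPM in RIP1i (SD, n = 3), a log2 fold change of 0.27 ± 0.067. Creld2 and Sdf2l1, chaperone-associated genes of the endoplasmic reticulum, had 0.19 ± 0.052 and 0.16 ± 0.046, and Asns, asparagine synthetase, had 0.48 ± 0.27. Camera gave an adjusted p of 0.00129, against an adjusted p of 0.809 with an estimated correlation, and no member passed when adjusted over the list alone. RIP1i replicate 2, at 0.27, set the difference of 0.13 (exact permutation p = 0.4), which was 0.013 without it (adjusted p = 0.358) and 0.21 without RIP1i replicate 3. Asns had 0.068 without RIP1i replicate 2. Without the 2 libraries of extreme stromal marker level the list difference was -0.0060 (camera adjusted p = 0.617). These 2 were also the lowest DMSO and the highest RIP1i library in this list, so leaving them out had to lower the difference.

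**Figure D2:**
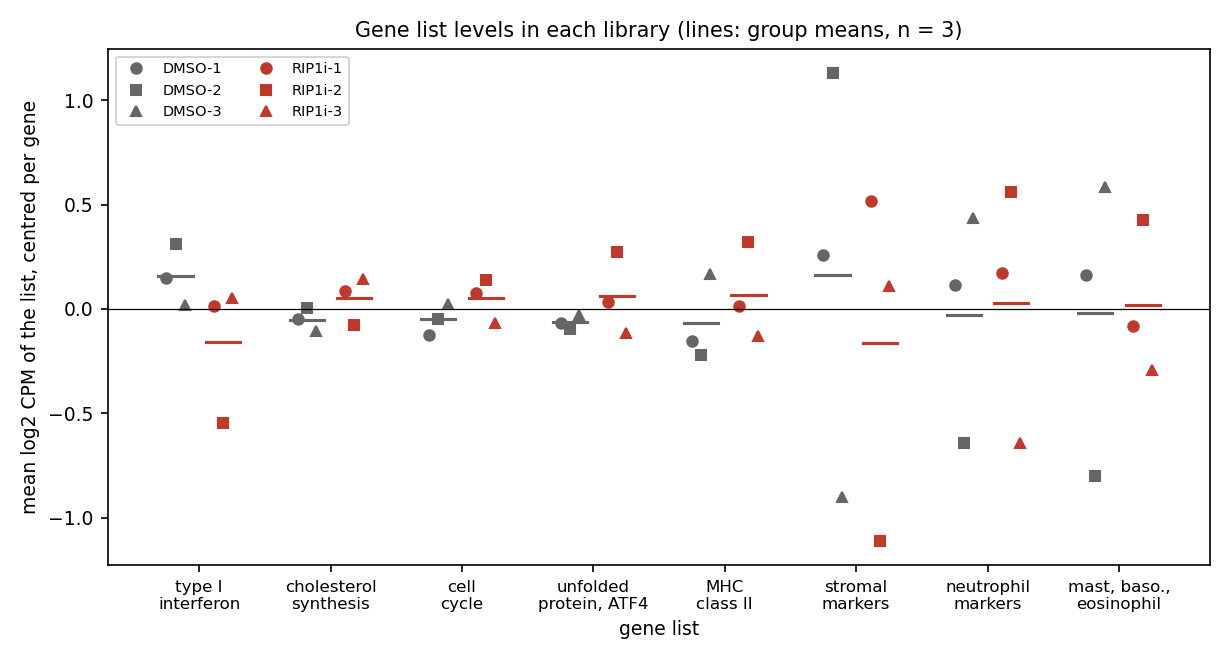
Level of 8 gene lists in each of the 6 libraries, as the mean log2 CPM over the genes of a list after centring each gene (vertical axis), with DMSO in grey, RIP1i in red, a symbol for each replicate number and lines for group means. The 4 lists on the left are those called by camera with the preset correlation, and their libraries overlap between groups. Stromal marker levels run from -1.11 in RIP1i replicate 2 to 1.13 in DMSO replicate 2.

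The other lists of signalling, metabolism and stress were not called. Of 20 NF-kB feedback and target genes, 12 were fitted higher (adjusted p = 0.296), with Nfkb2 at 0.10 ± 0.048 and Relb at 0.18 ± 0.085, both of the noncanonical branch. Of 13 chemokines for monocytes and neutrophils, 8 were fitted lower (adjusted p = 0.726), with Ccl8 at -0.47 ± 0.21. LXR target and lipid handling genes were split into 9 higher and 10 lower (adjusted p = 0.296), with Angptl4 at -0.38 ± 0.11 and Apoe, apolipoprotein E, at -0.52 ± 0.24. Apoe had -0.29 without RIP1i replicate 2 and -0.78 without RIP1i replicate 3. The LXR list was the 1 list of the 34 whose levels did not overlap between groups, at 0.028 ± 0.026 in DMSO and -0.028 ± 0.037 in RIP1i (SD, n = 3, exact permutation p = 0.1, the smallest possible). Chance alone would separate 10% of lists, so this separation does not stand out. Glycolysis and hypoxia genes were fitted lower in 19 of 25 (adjusted p = 0.473) and nuclear genes of oxidative phosphorylation higher in 23 of 27 (adjusted p = 0.0951), with the complex I gene Ndufa1 at 0.099 ± 0.039. NRF2 antioxidant genes were fitted higher in 12 of 17, aryl hydrocarbon receptor targets in 4 of 6, heat shock genes in 9 of 13 and lysosome and phagocytosis genes in 19 of 28, each with an adjusted p of 0.296. Heat shock and NRF2 genes passed without DMSO replicate 2 (camera adjusted p = 0.0413 and 0.0401). They also passed without the 2 libraries of extreme stromal marker level (camera adjusted p = 0.0163 and 0.00280). These 2 were the highest DMSO and the lowest RIP1i library in both lists, so leaving them out had to raise the differences. The differences of 0.034 and 0.036 in heat shock and NRF2 genes turned to -0.12 and -0.020 without DMSO replicate 3. With a surrogate variable both passed, as did the aryl hydrocarbon receptor targets (adjusted p = 0.0416, 0.0134 and 0.0416), but none of the 3 with an estimated correlation added (adjusted p = 0.816 each). Members of these lists were Nqo1, a quinone reductase, at 0.20 ± 0.082, the chaperonin Hspe1 at 0.20 ± 0.066, and Mfge8, a bridge for apoptotic cells, at 0.16 ± 0.050. Immediate-early genes were fitted higher in 10 of 15 (adjusted p = 0.460) and matrix remodelling and adhesion genes in 10 of 21 (adjusted p = 0.990), with Fos at -0.17 ± 0.057 and fibronectin, Fn1, at -0.47 ± 0.23, or -0.25 without RIP1i replicate 2.

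Markers of cell types were not called between the groups, but some of them varied widely between libraries of 1 group. All 12 stromal cell markers were fitted lower in RIP1i (adjusted p = 0.296), with Col1a1, a collagen chain of fibroblasts, at 29.9 ± 19.6 CPM in DMSO and 21.4 ± 10.9 CPM in RIP1i (SD, n = 3), a log2 fold change of -0.48 that was 0.10 without DMSO replicate 2. Their level ran from -0.90 to 1.13 in DMSO and from -1.11 to 0.52 in RIP1i, so the difference of -0.33 lay well inside the spread of either group (exact permutation p = 0.7). It was -0.86 without DMSO replicate 3 (camera adjusted p = 0.00166), 0.15 without DMSO replicate 2 and 0.14 without RIP1i replicate 2. Without both DMSO replicate 2 and RIP1i replicate 2 it was 0.62 (camera adjusted p = 0.00407). These 2 libraries were picked for the highest and lowest stromal level, so leaving them out had to raise the difference and tests nothing. Neutrophil and granulocyte precursor markers were fitted higher in 13 of 15 (adjusted p = 0.997) and ran from -0.64 to 0.44 in DMSO and from -0.64 to 0.56 in RIP1i. Mast cell, basophil and eosinophil markers were fitted lower in 6 of 10 (adjusted p = 0.990). Macrophage markers were fitted lower in 12 of 14 (adjusted p = 0.285), monocyte markers lower in 7 of 10 (adjusted p = 0.726), and dendritic cell markers higher in 11 of 14 (adjusted p = 0.303). B cell markers were fitted lower in 3 of 4 (adjusted p = 0.303) and T and NK cell markers higher in 3 of 6 (adjusted p = 0.751). Of the erythroid markers only Tfrc, the transferrin receptor gene, was tested, at 0.19 ± 0.070 with an edgeR adjusted p of 0.777 over all genes. With 1 tested member nothing is adjusted over the list alone, so its edgeR p of 0.026 there is the unadjusted p. Mitochondrial transcripts were fitted higher in 8 of 10 (adjusted p = 0.296) and cytosolic ribosomal protein genes lower in 22 of 24 (adjusted p = 0.475). For 5 uncalled lists the mean and median log2 fold change, the difference in list level and the direction of the test did not all have 1 sign. These were the T cell inhibitory ligands, the RIP1 components, the matrix remodelling genes, and the neutrophil and the mast cell, basophil and eosinophil markers.

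Between libraries, treatment was not the main axis of variation. The groups accounted for 15.7% of the variance of log2 CPM, against a mean of 20% over the 10 ways to split the 6 libraries into 2 sets of 3. Component 1, with 50.9% of the variance, put DMSO replicate 2 (-26.7) and RIP1i replicate 3 (-15.5) at one end and DMSO replicate 3 (19.5) and RIP1i replicate 2 (32.7) at the other. Component 2, with 14.9%, held the DMSO libraries at 6.67 to 11.1 and the RIP1i libraries at -20.8 to -3.11, a separation that chance gives any component in 10% of cases. Pearson correlations of log2 CPM across genes were 0.989 to 0.995 within groups and 0.986 to 0.996 between them.

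**Figure D3:**
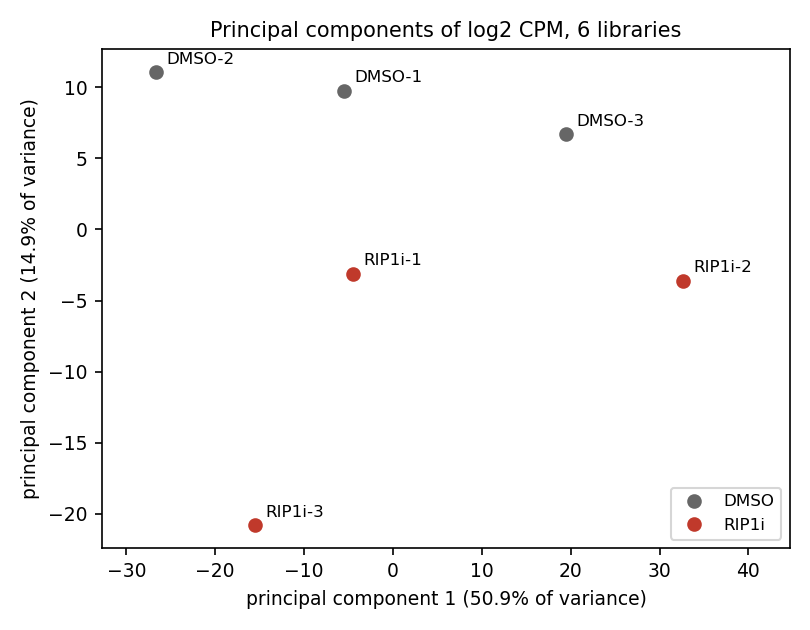
Components 1 (horizontal, 50.9% of the variance) and 2 (vertical, 14.9%) of log2 CPM over 14857 genes, with 1 point for each of the 3 DMSO (grey) and 3 RIP1i (red) libraries. Both groups are spread along component 1, and component 2 has the DMSO libraries above 6 and the RIP1i libraries below -3.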

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

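With edgeR the count of 0 changed genes, and of 0 higher, lower and 2-fold changed genes, held under every other scaling, filter, threshold, replicate block and omission tried. DESeq2 gave 2 changed genes (1 higher, 1 lower, 1 at least 2-fold), and limma-trend on FPKM without a filter gave 4 (2 higher, 2 lower), Mir6984, CT010471.2, Gm26491 and Llph-ps1, all at 0 counts in 1 group and at most 2 counts on average in the other and named after their values were seen. Genes at an unadjusted p under 0.05 numbered 413 to 1745, with 571 in DESeq2, 1451 on unfiltered FPKM, 1745 with the surrogate variable, 1237 without the 2 libraries of extreme stromal level, and 577 to 1052 with 1 library left out. The replicate number as a block gave 413 of them and 4 called lists. It changed no call among the 4 called lists. Same-numbered libraries correlated at 0.0058, -0.53 and -0.48 in their deviations from the group means, which gives no sign of pairing. With 3 libraries per group these values cannot exclude that same-numbered libraries share an origin. Lists called, 4 in the report, numbered 3 to 8 with 1 library left out (3 without RIP1i replicate 2, 7 without RIP1i replicate 3, 8 without DMSO replicate 2), 8 with the surrogate variable, 7 without the 2 extreme libraries, and 0 with the estimated correlation, with fry, or with the surrogate variable and an estimated correlation. For each of the 4 lists the adjusted p was 0.809 with the estimated correlation, 0.601 with fry and 0.816 with the surrogate variable and estimated correlation. With the surrogate variable and the preset correlation all 4 stayed called (adjusted p from 1.15e-11 for interferon to 0.00914 for the unfolded protein list). Without the 2 extreme libraries it was 0.242 for interferon, 0.144 for cell cycle and 0.617 for the unfolded protein list, while cholesterol synthesis kept its call (2.20e-08). With 1 library left out it ran from 3.76e-11 to 0.101 for cell cycle and from 1.02e-06 to 0.358 for the unfolded protein list, and both other lists kept their call. Stromal markers, uncalled and lower, were called higher without the 2 extreme libraries (camera adjusted p = 0.00407). Those 2 libraries were picked by this same level, so leaving them out had to raise the difference and tests nothing. Neutrophil markers, uncalled at a difference of 0.059, were called higher without RIP1i replicate 3 (0.39, camera adjusted p = 0.0247, the other omissions reaching 0.926). They were called lower without the 2 extreme libraries (-0.52, camera adjusted p = 0.00104). In the neutrophil, MHC class II and unfolded protein lists those 2 were the lowest DMSO and the highest RIP1i library. In the interferon, cholesterol, heat shock and NRF2 lists they were the highest DMSO and the lowest RIP1i library. Leaving them out therefore had to shift each of these differences in a fixed direction, whatever the cause. Over all 527 list alternatives, 45 changed the sign of the mean difference and 25 brought an uncalled list past the threshold: MHC class II 6 times, heat shock, NRF2 and ribosomal proteins 3 times each, neutrophil markers, stromal markers and mast cell, basophil and eosinophil markers 2 times each, and costimulatory ligands, oxidative phosphorylation, aryl hydrocarbon receptor targets and mitochondrial transcripts 1 time each. Over 2593 alternatives for 146 named genes, 59 changed sign and 1 changed a call, Arhgap4 in DESeq2. Omissions leave fewer libraries by construction, and for all other changes the cause was not tested. Low counts kept Il10, Arg1 and Cxcl9 out of the test, with 40 counts or fewer each over the 6 libraries. The surrogate variable and the omission of 2 libraries were chosen after seeing the data.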

Other observations

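The tests below were chosen after the results were seen, except the count of splits for gene lists and the stromal covariate for the interferon list, which were set down before their values were known. Transcripts of cells other than macrophages varied several-fold between libraries of 1 treatment. Col1a1 ran from 10.2 to 49.9 CPM over the 6 libraries, Col1a2, the other chain of collagen I, from 34.2 to 141 CPM, and the neutrophil granule gene Ngp from 26.6 to 99.8 CPM. S100a8 and S100a9, which encode the subunits of calprotectin, ran from 66.0 to 196 CPM and from 88.0 to 263 CPM, and the mast cell protease gene Cpa3 from 3.09 to 11.4 CPM. Ngp, S100a8, S100a9 and Cpa3 lie outside the naming rule and were chosen after their values were seen. The macrophage genes Lyz2 and Mmp12 ran from 39866 to 54100 CPM and from 9272 to 11619 CPM. The level of the mast cell, basophil and eosinophil markers ran opposite to that of the stromal markers over the 6 libraries (Pearson r = -0.894, exact permutation p = 0.0194, Benjamini-Hochberg adjusted p = 0.037 over 4 relations, and Spearman correlation = -0.771). Without DMSO replicate 3 and RIP1i replicate 2, the 2 libraries farthest from the median stromal level, r was -0.775. MHC class II genes also had r = -0.894 (exact permutation p = 0.0194, adjusted p = 0.037). This was -0.373 without DMSO replicate 3 and RIP1i replicate 2 and so rested in part on these. Type I interferon response genes had r = 0.801 (exact permutation p = 0.0278, adjusted p = 0.037), and 0.777 without DMSO replicate 3 and RIP1i replicate 2. Neutrophil markers had r = -0.754 (exact permutation p = 0.0972, adjusted p = 0.0972), and -0.286 without those 2 libraries. By Spearman correlation none of the 4 had an adjusted p under 0.05.

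A single transcript set RIP1i replicate 1 apart. CT010467.1, which resembles 45S ribosomal RNA and was chosen after its values were seen, stood at 8073 CPM there and at 179 to 570 CPM in the other 5 libraries. It took 0.799% of the counts of that library.

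The level of the stromal markers ran over 2.03 on the log2 scale within the DMSO libraries, against a difference of -0.33 between the groups. Treatment is constant within a group, so this range describes the spread and is no test of RIP1i. Library totals differed by 0.156 on the log2 scale, against 2.25 for the stromal marker level over the 6 libraries. That level is computed on CPM, which are already scaled by library size, so this comparison cannot decide on sequencing depth. A different share of stromal cells between libraries is a hypothesis. Another 20 stromal genes, not in the marker list, had a median Spearman correlation of 0.829 with the stromal marker level. The correlation of other genes with that level was not computed for comparison, so this value describes how stromal genes moved together and decides nothing. Whether such cells differed in number or in expression was not tested.

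The type I interferon response list, lower in RIP1i by -0.32 in its level, was weighed against 3 explanations. Without RIP1i replicate 2 the difference was -0.124, but that library was left out because it already stood apart, so this gives its weight and is no test of why it differs. With the stromal marker level as a covariate it was -0.240 ± 0.125 (SE). It did not shrink past the bound predicted for a different share of stromal cells, so that prediction was not met. It exceeded that bound by less than its SE, short of what was asked to count against a different share, so that explanation stays open. An effect of RIP1i stays open too. Of the 3 RIP1i libraries, 1 lay at or above the lowest DMSO library, short of the full separation that the test asked for, but 3 libraries per group are too few to decide from overlap.

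The 10 ways to split the 6 libraries into 2 sets of 3 are too few for a share under 0.05. With edgeR the real split gave 0 changed genes, 0 higher, 0 lower and 0 at least 2-fold, and the highest other split gave 0 for each, so 10 of the 10 splits gave as many, an outcome that a real count of 0 fixes in advance. At an unadjusted p under 0.05 the real split gave 923 genes and 3 of the 10 splits gave as many, with 2155 as the highest other. Camera with the preset correlation called 4 lists in the real split, 8 of the 10 splits gave as many, and the highest other gave 13. The most genes (2155, with 12 lists) came from setting DMSO replicates 1 and 2 and RIP1i replicate 3 against the rest. The most lists (13, with 1804 genes) came from setting DMSO replicates 1 and 3 and RIP1i replicate 2 against the rest. These 2 splits were picked as the highest of the 10, so their counts describe the spread and decide nothing about its source. With an estimated correlation, 0 lists were called in any split.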
